A study of Homo sapiens with 2 samples.

How the data were processed

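The samples were 2 RNA preparations from serum-starved THP1 cells, 1 with an inducible FXR1 shRNA and 1 with a control shRNA, each measured on 1 Affymetrix Human Gene 2.0 ST array. Per the labels' protocols, cells were lysed in a proteinase K buffer, RNA was isolated with Trizol, 100 ng of total RNA was amplified to cDNA, and 5.5 µg of cDNA was biotin-labelled. The deposited values are log2 probe set intensities, made with RMA (background correction, quantile normalisation and probe set summary) in Affymetrix Expression Console 1.3.0.187, per the submitters' processing notes. Quantile normalisation forces the arrays towards 1 distribution, so a change in total RNA per cell would not be visible. The sorted values of the arrays differed by at most 0.166. The genome build and the annotation release used for the summary are not given in the sources used here. Detection calls were not used here, so a level near the floor may be background. Values ran from 1.54 to 13.5 in the knockdown array and from 1.46 to 13.5 in the control array. For arrays, depth does not apply, and the number of arrays limits the precision.

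The table held 53617 probe sets. Genes were named through the platform annotation table supplied with the values, in which 16098 probe sets had 1 gene symbol, 0 had several and 37519 had none. All 14884 genes matched the RefSeq gene table (assembly GRCh38.p14) by gene ID. That table was used for current symbols, gene types, chromosomes and the order of neighbouring genes, and its coordinates are not given because the build behind the values is not known. Of the protein-coding genes in it, 59.4% had a named probe set here, so a gene without a value was not measured as unchanged.

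From the deposited log2 values, the difference between the arrays was computed as knockdown minus control, and a fold is 2 to the power of its size. A gene with several probe sets was represented by the one with the highest mean of both arrays. Genes entered if that mean was at or above 4.59, the median over all probe sets, which kept 10354 genes. Of these, 9168 are protein-coding, 566 are long non-coding and 368 are microRNA genes. With 1 array per group, no test between groups was possible and genes were ranked by size, with a threshold of 2-fold (1 on the log2 scale).

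The 38 gene lists, the thresholds, the rule for naming genes and most alternatives were fixed before the data were examined. A list with at least 5 genes above the floor was described by its median difference. That median was placed among the medians of 10000 random lists of the same size, drawn to match its expression levels in 20 bins of equal size, and the list was called apart outside percentiles 2.5 to 97.5. The percentile describes these arrays and is not a p-value. Chromosomes were treated in the same way. The genes named in the text are FMR1 of the FXR family, the 12 highest and 12 lowest genes (leaving out the symbol prefixes of unnamed loci, microRNAs, small nucleolar, Cajal body and nuclear RNAs, Y RNAs, ribosomal and transfer RNAs, olfactory receptors and immune receptor segments, and symbols of open reading frames and antisense, intronic or overlapping transcripts; vault RNAs were not left out), up to 4 genes of largest difference in each list that stood apart or held a 2-fold gene, up to 2 in every other list, and a fixed set (TNF, EIF4EBP1, PARN, MYC and CD14). Other genes that the text names were chosen after their values were seen, and so was the scan of windows of 40 neighbouring genes, moved 10 genes at a time.

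Alternatives covered the scaling (centring, removal of a loess trend with span 0.3 and quantile normalisation again), the choice of probe set, the floor, the fold threshold, the mean in place of the median, and unmatched random lists. Restricting genes to protein-coding ones, leaving out the genes of the shifted runs and removing host transcripts and assembly factors from lists were added after the data were seen. The steps on genes and lists were tested on simulated data built from these 10354 genes. Noise was drawn independently for each gene from a normal distribution. Its width at each level came from the median absolute deviation of the observed differences, so their tails were left out. Of simulated genes changed 4-fold, 100% passed the 2-fold threshold, against 52.2% of those changed 2-fold and 5.97% of those changed 1.5-fold, and 7 of 10154 unchanged genes passed it. Without the tails, that last count does not estimate false 2-fold differences between the real arrays. Of 310 unchanged simulated lists 5.81% were called apart, against 75.5% of lists shifted by 0.2. These lists held randomly drawn genes, so correlation between the members of a real list was not covered. The window scan, simulated on 10349 placed genes with 200 shuffles each, found 9 of 10 simulated runs shifted by 0.25, and it gave 4 false runs in 10 simulations without any shift. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures used matplotlib 3.10.9.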

Results

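Gene expression was measured in THP1 cells, an established human monocytic leukaemia line, after 2 days without serum. 1 population stably carried a doxycycline-inducible short hairpin RNA (shRNA) against FXR1, an RNA-binding protein of the fragile X family that takes part in microRNA-guided and AU-rich-element-guided control of mRNAs. The other carried a control shRNA. Both received doxycycline at 1 µg/ml throughout, grew for 3 days in serum while the shRNAs were induced, and were then starved of serum to bring them to quiescence (G0). Total RNA from each population was hybridised to 1 Affymetrix Human Gene 2.0 ST array, so each group had 1 array and there were no replicates. The number of arrays limits the precision. Every difference below compares these 2 arrays, has no replicate check and carries no p-value. Values are log2 expression levels, and differences are knockdown minus control. The array medians were 4.59 in the knockdown and 4.58 in the control. The arrays correlated at r = 0.985 across all probe sets, which are not independent replicates.

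The knockdown itself could not be checked in these values. FXR1 and its paralog FXR2 were not analysed here, because no probe set carried their symbols in the gene table used. FMR1, the remaining member of the family, was 1.48-fold lower in the knockdown array (log2 7.74 against 8.31, a difference of -0.57). Genes with a mean log2 level of 8 to 9 had a median difference of -0.19, so part of this is a shift that genes of its level share. Over the alternative settings the FMR1 difference ran from -0.57 to -0.38.

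The comparison asked which transcripts differ between quiescent cells with and without the FXR1 shRNA. The chemokine genes CCL2 and CXCL8, the macrophage gene SPP1 and the granule protease gene PRTN3 were among the highest differences, and the surface protein genes CD93 and NCAM1 and the macrophage gene MPEG1 among the lowest. Of 10354 genes above the expression floor, 33 were at least 2-fold higher and 53 at least 2-fold lower in the knockdown array, together 0.831% of the genes. At 1.5-fold the counts were 224 higher and 556 lower. The excess of lower genes followed the scaling. The median difference over these genes was -0.10, and 63.8% of them were lower in the knockdown array. Once the differences were centred on that median, the 2-fold counts became 48 higher and 34 lower. They were 50 and 36 after a trend with expression level was removed, and 44 and 37 after the arrays were quantile-normalised again. The share of higher genes among those 2-fold apart thus went from 38.4% to 58.5%, 58.1% and 54.3%. Gene group shifts are therefore given beside the median of random gene lists with matched expression, which carry the same overall shift. Differences of single genes are given as deposited, so they include that shift.

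The highest difference belonged to VTRNA2-1, a vault-type non-coding RNA known to bind the kinase PKR, at 7.57-fold (a difference of 2.92 on the log2 scale). PRTN3, which encodes the neutrophil granule protease proteinase 3, was 4.35-fold higher and MT1G, a metal-binding metallothionein, 4.24-fold higher. SLAMF8, a myeloid surface receptor, was 4.14-fold higher and SPP1, which encodes osteopontin, 4.08-fold higher. The monocyte-attracting chemokine CCL2 was 4.02-fold higher and the neutrophil-attracting chemokine CXCL8 3.77-fold higher. THBS1 (thrombospondin 1) was 3.17-fold, IRS2 (an adaptor of insulin receptor signalling) 2.89-fold, DSG2 (a desmosomal cadherin) 2.86-fold and UNC13D (a factor in granule exocytosis) 2.63-fold higher. HCP5, a long non-coding RNA of the HLA region, was 3.21-fold higher on its brightest probe set (difference 1.68), while its other 2 probe sets gave 0.64 and 0.76.

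The lowest difference was that of CD93, a surface glycoprotein of myeloid and early haematopoietic cells, which was 5.43-fold lower (log2 6.96 against 9.40). NCAM1, the adhesion molecule CD56, was 4.47-fold lower and CDCA7, a MYC and E2F target, 3.11-fold lower. MPEG1, the macrophage pore-forming protein perforin-2, was 3.03-fold lower at a high level (log2 8.52 against 10.1). The transcription factor genes EBF3, NEUROG3, BCL11A and ZNF141 were 3.02-fold, 2.74-fold, 2.70-fold and 2.62-fold lower. TOM1L1 (endosomal sorting) was 2.84-fold, SDHAF3 (assembly of succinate dehydrogenase) 2.73-fold and OFD1 (centrioles and cilia) 2.64-fold lower. SPEF2, a sperm flagellar gene, was 3.06-fold lower and lies in a stretch of chromosome 5 whose genes were lower together, described at the end. The knockdown levels of SPEF2 and SDHAF3 and the control level of DSG2 lay under the floor of 4.59, where signal was not shown to exceed background, so their folds are uncertain, as are those of SESN3, VCAN, MIR4299, MIR2052HG and MIR17HG below for the same reason.

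**Figure D1:**
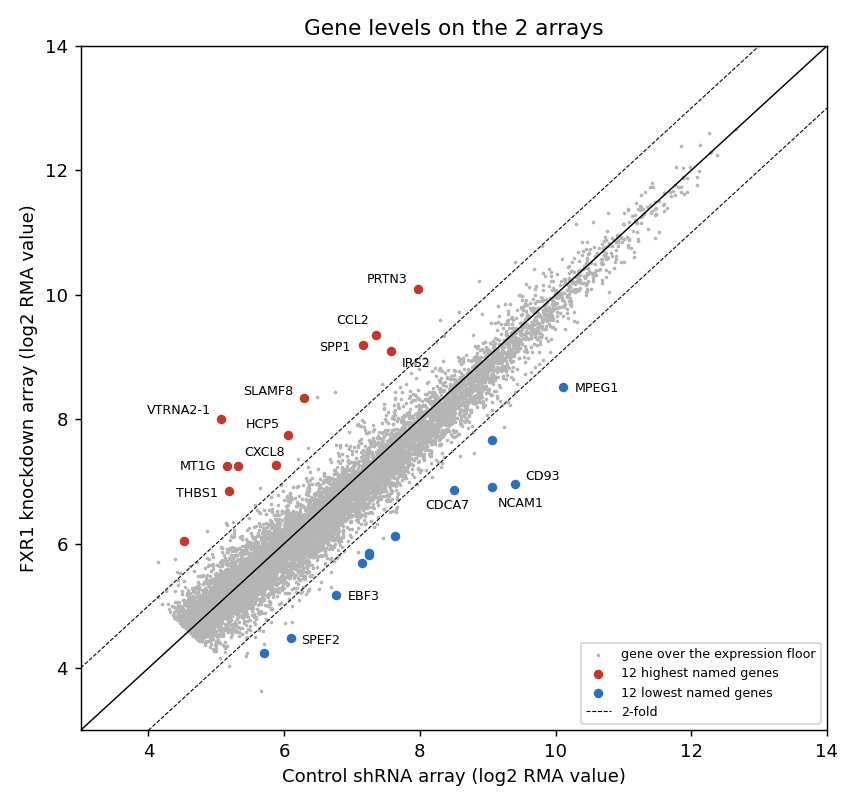
Log2 level of each gene above the expression floor in the control array (horizontal) and the knockdown array (vertical), 1 array per group. Red and blue points are the 12 highest and 12 lowest genes of the naming rule, the solid line marks equal levels and the dashed lines 2-fold differences; VTRNA2-1 lies farthest above at 7.57-fold and CD93 farthest below at 5.43-fold.

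Cell-cycle genes were lower as a group. For DNA replication and the G1/S transition, 38 of 39 genes were lower, with a median difference of -0.35 against -0.15 for matched random lists, and 7 of them were at least 1.5-fold lower. CCNE1 (cyclin E1) had a difference of -0.84, TIPIN -0.71, E2F3 -0.70 and DBF4 -0.69. For G2/M and mitosis, 47 of 54 genes were lower with a median of -0.34 against -0.16. HMMR, a spindle-associated hyaluronan receptor, was 2.27-fold lower, and BIRC5 (survivin), LMNB1 (lamin B1) and CDC25C had differences of -0.88, -0.84 and -0.69. Both medians lay below all 10000 random lists. HMMR dropped just under 2-fold, to -0.99, once the trend with level was removed.

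Genes of cholesterol synthesis and uptake were lower in 19 of 20 cases, with a median of -0.39 against -0.14, below all random lists. The largest differences were in ACAT2 (-1.02), which makes acetoacetyl-CoA, and in the mevalonate pathway enzymes MVD (-0.99), MVK (-0.92) and PMVK (-0.67). Of 75 genes with mitochondrial ribosomal protein symbols, 62 were lower, with a median of -0.25 against -0.13, at percentile 0.07 of the random lists. MRPL27 had a difference of -0.75 and MRPL39, MRPS23 and MRPL16 had -0.72, -0.72 and -0.71. Cytosolic ribosomal protein genes did not stand apart: their median over 46 genes was -0.15 against -0.12, at percentile 27.5, with RPS15A and RPL35A both at -0.75.

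NF-kB target and inflammatory genes were higher as a group. Of 26 measured genes, 21 were higher, with a median of 0.24 against -0.13, above all random lists. Besides CCL2 and CXCL8, the chemokine CCL5 was 2.17-fold higher and the leukocyte adhesion receptor ICAM1 2.17-fold higher. TNF, whose mRNA is a known target of AU-rich-element control, went the other way with a difference of -0.99. Its 8 probe sets gave -0.99 in 7 identical copies and -1.08 in the other. Monocyte and macrophage markers had a median of 0.09 against -0.09, at percentile 99.9, with 22 of 33 genes higher. SPP1 led them, CTSD (cathepsin D) had a difference of 0.84 and the monocyte receptor CD14 0.74. Members of the same list went the other way, among them CCR2, the receptor of CCL2 (2.53-fold lower), and VCAN, which encodes versican (2.22-fold lower). Type I interferon response genes did not stand apart: their median was -0.16 against -0.11 over 35 genes, at percentile 19.995, with MX2 2.23-fold higher and HERC5, IFITM3 and RIGI at -0.73, -0.70 and -0.60.

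Adhesion, integrin and matrix genes had a median of 0.15 against -0.14, above all random lists, with 17 of 24 genes higher. THBS1 led, TIMP3, an inhibitor of matrix proteases, was 2.22-fold higher, CD44 had a difference of 0.58 and SELPLG, the P-selectin ligand, -0.64. Genes of the unfolded protein and integrated stress responses had a median of 0.12 against -0.15, also above all random lists, although none of the 29 genes reached 1.5-fold and only 16 were higher. The chaperone gene HYOU1 and the transcription factor gene XBP1 had differences of 0.51 and 0.45, and EIF2AK4 and CTH had -0.44 and -0.44. Heat shock and oxidative stress genes had a median of 0.09 against -0.13 (percentile 99.9, 13 of 21 higher). Metallothioneins led this list, with MT1G at 2.08, MT2A at 0.88 and MT1F at 0.68, while the chaperone HSPH1 had -0.68. Metallothionein genes are near-identical copies, so the probe sets may not tell their transcripts apart. Lysosome and autophagy genes had a median of 0.05 against -0.13 (percentile 99.9, 21 of 34 higher). Its largest differences went both ways. The lysosomal proteases CTSD and CTSH had 0.84 and 0.72, whereas the autophagosome genes GABARAPL2 and ATG16L1 had -0.87 and -0.83.

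Probe sets with microRNA gene symbols had a median of 0.03 against -0.08 over 382 genes, above all random lists, with 205 higher and 176 lower. The random lists were drawn mostly from protein-coding genes, whose median was -0.11, whereas the median over all probe sets was -0.01. A comparison with other non-coding genes was not made. MIR891A was 3.67-fold and MIR4299 2.97-fold higher. The lowest 2, MIR2052HG (4.06-fold lower) and MIR17HG (2.49-fold lower), are long non-coding host transcripts and not precursors. MIR17HG hosts the miR-17-92 cluster. Mature microRNAs were not measured separately.

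**Figure D2:**
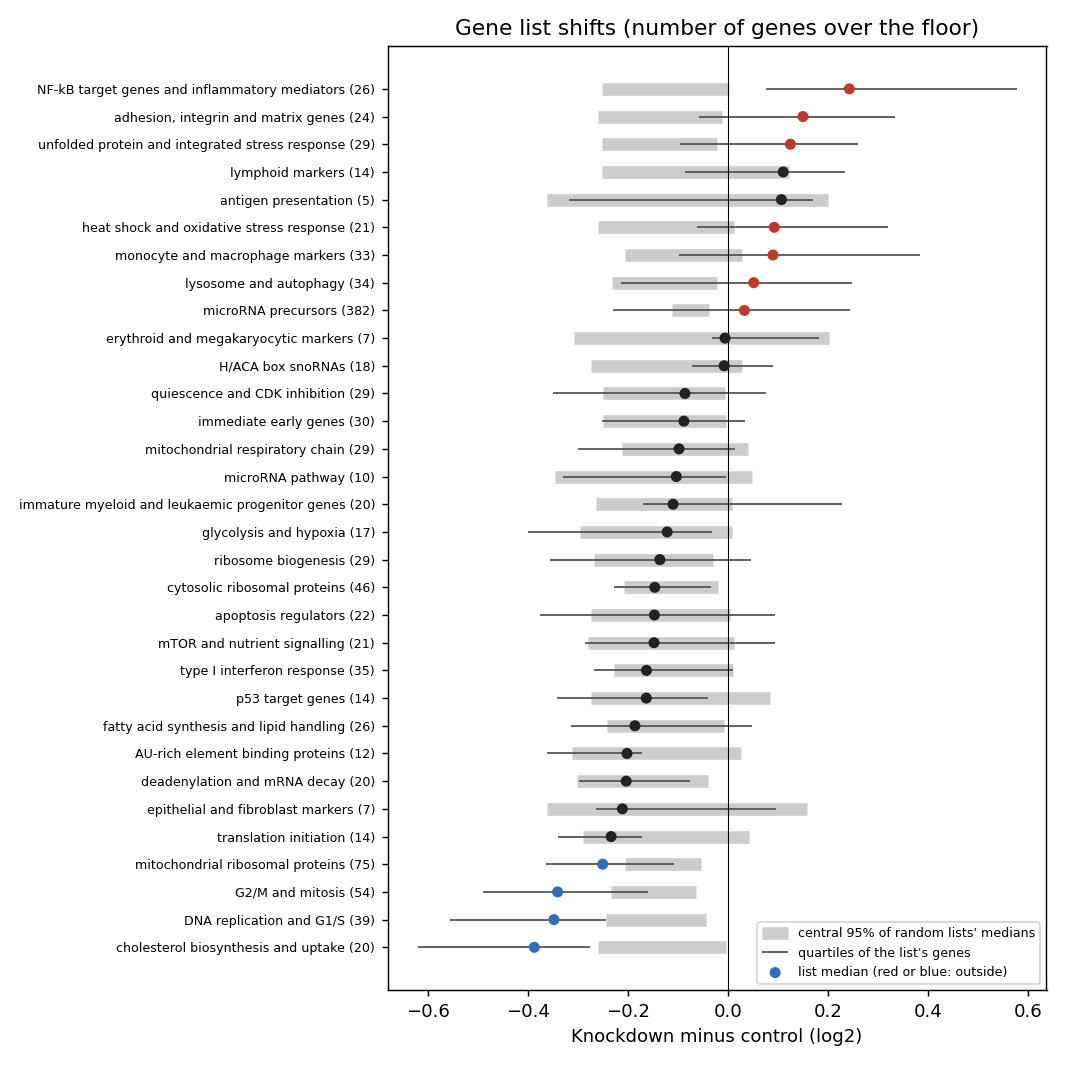
Median difference, knockdown minus control on the log2 scale, of each of the 32 gene lists with at least 5 genes above the floor (number of genes in brackets). Grey bars span the central 95% of medians of 10000 expression-matched random lists and thin lines the quartiles of the list's genes; 4 lists (blue) lie below and 7 (red) above the bars. The H/ACA box list holds small Cajal body RNAs only.

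**Figure D3:**
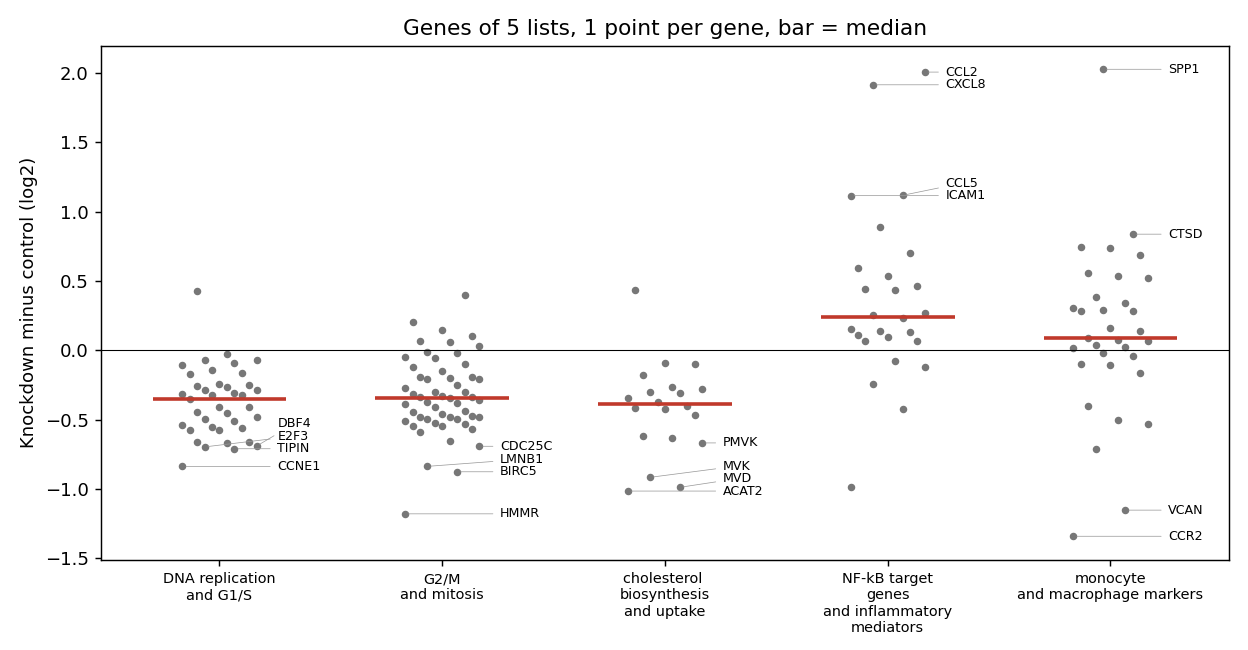
Difference of each gene, knockdown minus control on the log2 scale, in 5 of the lists, with the median as a red bar and the 4 genes of largest size labelled. The G1/S median is -0.35, the G2/M median -0.34, the cholesterol median -0.39, the NF-kB median 0.24 and the macrophage median 0.09.

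Genes of the RNA pathways in which FXR1 acts did not stand apart from random lists. The microRNA pathway had a median of -0.10 against -0.15 over 10 genes (percentile 67.3), with TNRC6B at -0.54 and TNRC6C at -0.37, 2 scaffold proteins of the silencing complex. AU-rich element binding proteins had -0.20 against -0.15 over 12 genes (percentile 27.4), with TIA1 at -0.41 and RC3H2 at -0.39. Deadenylation and mRNA decay genes had -0.20 against -0.17 over 20 genes (percentile 30.8), with UPF2 at -0.61 and EXOSC3 at -0.52. PARN, the poly(A)-specific ribonuclease, had a difference of -0.31, while genes at its level (log2 8 to 9) had a median of -0.19. Translation initiation genes had -0.23 against -0.13 over 14 genes (percentile 9.96). Among them EIF4EBP1, the repressor of the cap-binding protein eIF4E, was 1.57-fold lower and EIF5A had 0.56. AGO2, EIF4G2 and the cell-cycle inhibitor gene CDKN1A were not analysed here, for the same reason as FXR1. Genes of mTOR and nutrient signalling had -0.15 against -0.14 over 21 genes (percentile 43.3). IRS2 and SESN3, a sestrin, stood out in it at 2.89-fold and 2.17-fold higher, RRAGC had 0.56 and DEPTOR -0.42. RRAGC lies in a stretch of chromosome 1 whose genes were higher together.

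Other lists that did not stand apart covered growth control, metabolism and cell death. Quiescence and CDK inhibitor genes had a median of -0.09 against -0.13 over 29 genes (percentile 76.3), with YPEL3 at -0.65 and CCNG2 at -0.57. Targets of p53 had -0.16 against -0.09 over 14 genes (percentile 21.9), with TP53I3 at -0.83 and TRIAP1 at -0.80. Immediate early genes had -0.09 against -0.13 over 30 genes (percentile 74.7). In that list DUSP5 had -0.80 and EGR1 -0.67, the latter -0.23 on its dimmer probe set, and MYC had -0.03, a value that turned positive under all 3 other scalings. Ribosome biogenesis genes had -0.14 against -0.16 over 29 genes (percentile 61.5), with RRS1 at -0.87 and LYAR at -0.53. Fatty acid and lipid handling genes had -0.19 against -0.13 over 26 genes (percentile 16.3), with the lipoprotein lipase gene LPL at 0.89 and PPARD at -0.58. Glycolysis and hypoxia genes had -0.12 against -0.14 over 17 genes (percentile 60.5), with LDHA at -0.53 and BNIP3 at -0.44. Respiratory chain genes had -0.10 against -0.09 over 29 genes (percentile 44.5). SDHAF3 was the lowest of them, UQCRH had 0.55, and the assembly factors SDHAF4 and NDUFAF8 had -0.49 and -0.49. UQCRH and the CTH gene named above lie in another stretch of chromosome 1 whose median was higher. CTH, at -0.44, went against that direction. Apoptosis regulators had -0.15 against -0.14 over 22 genes (percentile 46.6), with BIRC5 at -0.88 and BAK1 at -0.63. Small Cajal body RNAs had -0.01 against -0.13 over 18 genes (percentile 93.8), with SCARNA11 at -0.46 and SCARNA9 at -0.38.

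The lists of immature myeloid, lymphoid, erythroid, epithelial and antigen presentation genes did not stand apart as groups, although single members differed widely. Immature myeloid and progenitor genes had a median of -0.11 against -0.14 over 20 genes (percentile 64.1), with large differences both ways. PRTN3 and CTSG, which encodes the granule protease cathepsin G, were 4.35-fold and 1.99-fold higher. CD93 and MEF2C were 5.43-fold and 2.14-fold lower, MEF2C with -0.60 when its 2 probe sets were averaged. Lymphoid markers had 0.11 against -0.06 over 14 genes (percentile 96.7, and up to 98.8 in other settings), with NCAM1 4.47-fold lower, GNLY at 0.61, NKG7 at -0.61 and CD2 at 0.33. Erythroid and megakaryocytic markers had -0.01 against -0.05 over 7 genes (percentile 63.5), with GATA1 at 0.27 and EPB42 at 0.20. Epithelial and fibroblast markers had -0.21 against -0.09 over 7 genes (percentile 17.2), with TAGLN at -0.69 and THY1 at 0.31. Antigen presentation genes had 0.11 against -0.09 over 5 genes (percentile 91.4), with ERAP2 at -0.37 and CD1D at 0.36. In all, 11 of 32 lists stood apart, and 1.6 would be outside by chance if members varied independently. The lists of FXR family genes, C/D box snoRNAs, small nuclear RNAs, replication-dependent histones, proteasome subunits and mitochondrially encoded transcripts had fewer than 5 measured genes and were not described.

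Probe sets of the same gene gave the only repeat measurement, which covers probe noise and not the spread between cultures. Across 380 genes whose probe sets above the floor were not all identical, the differences of the 2 brightest correlated at r = 0.43 (rho = 0.35). These genes are not independent replicates. In some of them, such as TNF and SNAR-C1, the 2 brightest were themselves identical copies, so their agreement was fixed in advance. Such copies count as agreement in the correlation, the gap and the sign counts. The gap between the 2 brightest had an SD of 0.34, close to the SD of 0.33 of all gene differences. Where the brightest probe set was at least 1.5-fold apart, the next one had the same sign in 20 of 24 genes, and over all the genes compared it did in 245 of 380.

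Chromosome medians were compared in the same way. The 1030 genes of chromosome 1 had a median of -0.02 against -0.10 for matched lists, above all 10000 of them. Chromosome 5 had -0.14 against -0.10 (percentile 0.57), chromosome 18 -0.18 against -0.12 (percentile 2.15) and chromosome X -0.13 against -0.09 (percentile 2.35), and these 3 were lost under some settings. A scan of 957 windows of 40 neighbouring genes, chosen after the chromosome medians were seen, located the shift. After removal of the trend with level, 5 runs of windows passed limits that 95% of 1000 shuffles of the gene order did not reach. On chromosome 1, the runs from AGRN to MIR4632 (100 genes), BSDC1 to ZFP69 (60 genes), KDM4A-AS1 to FPGT-TNNI3K (100 genes) and KLHDC9 to GPR52 (60 genes) had medians of 0.25, 0.22, 0.23 and 0.17. The shares of higher genes in them were 79%, 78.3%, 75% and 65%. Run ends are window edges, and stretches inside went the other way. Near the end of the third run, the neighbours DEPDC1, LRRC40, SRSF11 and ANKRD13C had -0.75, -0.78, -0.69 and -0.73. Near the start of the fourth, USP21 and TOMM40L had -0.69 and -0.89. The window from HSPA6 to SUCO was highest at 0.45, or 1.37-fold, with 32 of 40 genes higher, while the highest window of any shuffle was 0.24. On chromosome 5, the run from LRRC14B to ANXA2R-OT1 (60 genes) had a median of -0.25. Its lowest window, at -0.271, barely passed the lowest of any shuffle, at -0.267.

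**Figure D4:**
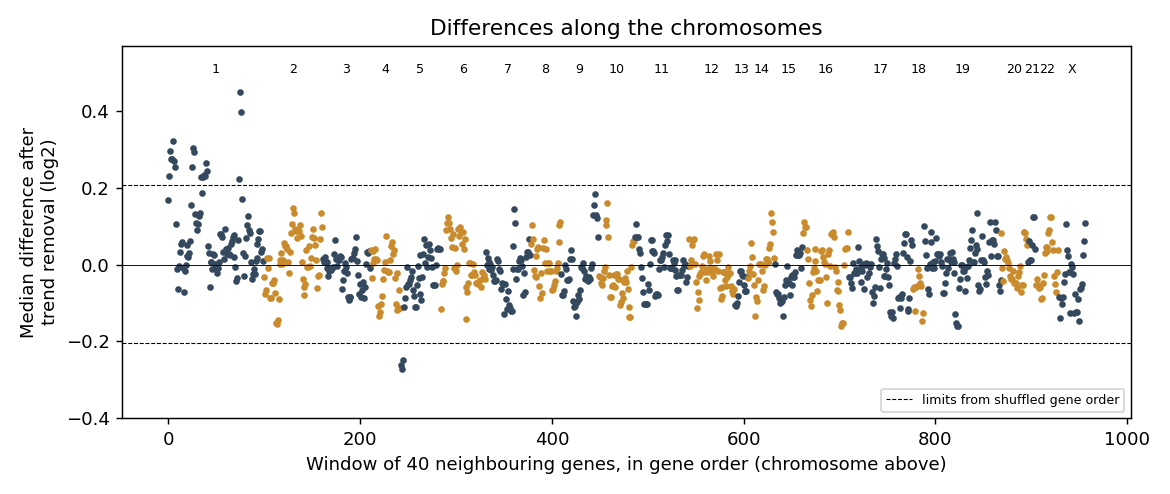
Median difference, knockdown minus control on the log2 scale after removal of the trend with level, in each window of 40 neighbouring genes, ordered along the chromosomes (numbers above). Dashed lines are the limits from 1000 shuffles of the gene order; windows of chromosome 1 reach 0.45 and those of chromosome 5 reach -0.27.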

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

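Probe sets without a gene symbol were not used in the gene comparison, and they differed between the arrays more often than named ones. Among 15723 such probe sets above the floor, 198 were at least 2-fold higher and 277 at least 2-fold lower in the knockdown array, or 3.02% of them. Among 11086 probe sets with a symbol the counts were 33 and 57, or 0.812%. The widest differences were those of probe set 16675239, 20.1-fold lower (log2 6.61 against 10.9), and probe set 16963901, 11.6-fold lower. In the other direction, probe set 16771526 was 13.1-fold higher and probe set 17100701 9.05-fold higher. What these probe sets measure was not determined here. Control probe sets were not separated from them, so neither the share nor these folds can be read as differences of transcripts. No explanation for the higher share was tested. A search for outlying arrays was not possible with 1 array per group.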

How the results depend on the processing

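With 1 array per group, no alternative measures the spread between cultures, and signal near the floor limits the dimmer genes. Settings restricted to protein-coding genes or leaving out the genes of the shifted runs were chosen after seeing the data. Centring moves a list and its random lists by the same amount, so it could not change whether a list stood apart. Trend removal was a weak check on lists, since the random lists were already matched on level. The 11 lists that stood apart kept their sign and their place outside the central 95% under each setting that was run, as did the median of chromosome 1 relative to matched lists; that median itself ran from -0.07 to 0.08. For the remaining lists the exceptions were lymphoid markers, which stood apart higher against unmatched lists (0.11, percentile 98.8) and without the run genes (0.13), and mTOR genes, whose mean (0.038, percentile 98.7) stood apart where their median did not. At the 75th-percentile floor 28 lists had enough genes.

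The 2-fold counts moved to 21 higher and 28 lower with the floor at the 75th percentile and to 224 and 556 at 1.5-fold, both by construction. The trend removal gave 50 higher and centring 34 lower, since each removes the overall shift. The call for chromosome 18 was lost with a floor on the higher array (-0.16), with the mean (-0.16), with averaged probe sets (-0.17), without a floor (-0.076) and without the run genes (-0.18). That for chromosome 5 was lost at the higher floor (-0.19), with protein-coding genes only (-0.15) and without the run genes (-0.13). That for chromosome X was lost after quantile normalisation (-0.043), with the mean (-0.11), with averaged probe sets (-0.13), without a floor (-0.034), with unmatched lists (-0.13), after trend removal (-0.033) and without the run genes (-0.13). Leaving out the run genes takes the lower run out of chromosome 5, so a weaker call there was built in. The cause of the other losses was not tested. The correlation between probe sets of the same gene was 0.747 at the 75th-percentile floor and 0.313 without a floor, again with identical copies kept. Among named genes, ACAT2, HMMR, MEF2C and HCP5 fell under 2-fold in at least 1 setting, and CTSG and MT2A passed it. Keeping probe sets with several symbols changed nothing, because there were none.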

Other observations

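The gene families and the tests in this part were chosen after the results were seen, except the chromosome medians, which were planned. Genes with symbols that start with ZNF, most of which encode zinc finger proteins, were lower as a family. Of 388 above the floor, 281 were lower, with a median of -0.17 against -0.09 for matched random lists, below all 10000 of them. After removal of the trend with level it was -0.08, again below all of them. At least 1.5-fold differences were lower in 43 and higher in 4. The 388 include antisense and divergent transcripts; the 376 protein-coding members alone had a median of -0.17, with 273 lower. The family's large cluster on chromosome 19 did not account for this alone, since 179 members there had a median of -0.16 and 209 members elsewhere -0.17. Beside ZNF141, ZNF514 was 2.35-fold, ZNF544 2.22-fold and ZNF223 2.17-fold lower. Whether probe sets of these similar genes share signal was not tested.

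Metallothioneins and cathepsins, some of which belong to the heat shock, lysosome and macrophage lists that stood apart, were higher as families; those lists were not recomputed without them. 5 of 6 metallothioneins were higher, with a median of 0.64, including MT1X at 0.60, while MT1E had -0.60. Of 16 genes with cathepsin symbols, 12 were higher, with a median of 0.11 against -0.12 (percentile 99.6). Within the macrophage list the calprotectin genes S100A8 and S100A9 had -0.54 and -0.40 and S100A12 had -0.71, opposite to CD14, CD80 (0.75) and TLR4 (0.69). The FLT3 gene, a receptor of myeloid progenitors, had -0.96.

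The shifted runs of neighbouring genes were weighed first. Of 1000 shuffles of the gene order, 0 had a window as high as the highest, so chance order does not account for it. The trend with level does not account for chromosome 1, whose median lay at percentile 100 of lists matched on level, both as deposited and after the trend was removed. For chromosome 5 these percentiles were 0.57 and 1.44, so the trend does not account for its shift either, although that call was lost in 3 alternatives that left the trend as it was. A difference in copy number between the 2 cell populations is a candidate explanation. Probe sets without a symbol were placed by their number between named ones, not by coordinate (98.5% of neighbouring named numbers were on the same chromosome), and control probe sets were not separated from them. So placed, they shifted the same way, beyond the central 95% of random draws, in 4 of the 5 runs (medians 0.16, 0.17, 0.14 and -0.15), and not in the run from BSDC1 to ZFP69 (0.04, percentile 74.8). A regional change in transcription could shift these probe sets in the same way, so their shift does not favour a copy number difference over it. Such a change without a copy number change stays open, and so does a response to the FXR1 shRNA. The share of 75% of the runs' genes in the run's direction cannot separate these, since the runs were picked by that direction. The lowest window of the chromosome 5 run passed the most extreme shuffle only narrowly, and the scan gave 4 false runs in 10 simulations without a shift.

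For the lower cell-cycle genes, the 93 genes of both lists had a median of -0.35, below all random lists, with 85 lower. The median was -0.20 after the trend with level was removed, with matched random lists between -0.07 and 0.06, so the trend is not the whole of it. Of the 93 genes, 90 lay outside the shifted runs of neighbouring genes, so leaving out the others could hardly move the median, which was then -0.348. The runs hold too few of these genes to account for the shift. A difference between the 2 cultures unrelated to FXR1, such as the depth of growth arrest after serum removal, cannot be told apart from a response to the shRNA, because there was 1 array per group. A lower cell-cycle programme in the FXR1 knockdown therefore stays a hypothesis, as the knockdown itself was not measured here.

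For the higher NF-kB target and macrophage genes, the 59 genes of both lists had a median of 0.15, above all random lists, with 43 higher. The trend with level was negative from log2 5 upward, with median differences of -0.03 at levels of 5 to 6 and -0.19 at 7 to 8. At these levels it lowers genes and could not produce a higher median. Removal of the trend, which gave a median of 0.29, was therefore not a separate test. Without the CCL and CXCL genes the median was 0.13 over 51 genes, above all random lists, so these genes are not the whole of the shift. The 33 macrophage markers hold none of them and stood apart alone (percentile 99.9), which made this result likely beforehand. The NF-kB list alone was not recomputed without them, so cross-hybridisation within chemokine families was not tested for that list. A difference between the 2 cultures unrelated to FXR1, such as spontaneous activation or differentiation in 1 of them, cannot be told apart from a response to the shRNA with 1 array per group. A response to loss of FXR1 may explain the shift, and it stays a hypothesis. TNF, at -0.99, was among the 5 of 26 NF-kB genes that were lower.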
